A study of Homo sapiens with 9 samples.

How the data were processed

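Total RNA from SW1783 cells, an established human glioma cell line, was measured on 9 Affymetrix expression arrays. Cells had been transfected for 24 h with a synthetic duplex at 50 nM, which was miR-376a*A, its form miR-376a*G, or a control miRNA, with 3 arrays per group from separate biological replicates, per the labels. The RNA was amplified and labelled with Biotin-ULS, per the labels' protocols, and GCOS version 1.4.0.036 is named in the submitters' processing notes.

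The values deposited by the authors are linear signal intensities, given for each of 54675 probe sets and 9 arrays. The mean of each deposited array after trimming 2% at each end was between 100.01 and 100.013 signal units, so the arrays had been scaled to a common level before deposit. How probe signals were summarised and how background was removed are not given in the sources used here, and no detection calls were used here. Such scaling equalises average brightness, so a change common to most transcripts of an array would not be seen.

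Intensities were turned into log2(signal + 16). The array medians on that scale then ranged over 0.20, above the limit of 0.1 set before the data were examined, and the log2 values were therefore quantile normalized between arrays. A fold change is given on this scale and understates the change of dim genes. Probe sets were named from the platform annotation: 41097 had 1 gene symbol, 1801 had several and 11777 had none in the table used here. Of those with 1 symbol, 41043 had a gene ID in the RefSeq gene table of GRCh38.p14, with 0 symbols changed, and 54 kept the platform's symbol. Probe sets with a mean over the 9 arrays below the 50th percentile of all probe sets (5.17 on the log2 scale) were left out, and each gene was represented by its brightest remaining probe set. This gave 12505 genes, of which 5993 had more than 1 remaining probe set. No coordinates are given, since the files name no genome build.

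Differences between groups were tested in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend). The 3 groups were fitted together and shared the estimate of the spread, and p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Gene lists, 28 in all, were fixed before the data were examined. The 23 lists with at least 5 measured genes were tested with limma's camera with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. For the cholesterol list the estimate was -0.0018, below the preset value. Its camera adjusted p with miR-376a*A against control still rose from 0.0193 to 0.138. A larger p with an estimated correlation is therefore not by itself a sign that the genes of a list are correlated. All lists also have a count adjusted over the list alone. Errors are standard errors of the log2 fold change (SE) or standard deviations over 3 arrays (SD). The number of arrays limits the precision: an exact test of 3 against 3 arrays alone cannot give a p below 0.1.

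Genes are named by a rule fixed before the data were examined: the 12 largest rises and 12 largest falls of each comparison among genes past the threshold whose arrays did not overlap between the groups, RAP2A in every comparison, and up to 4 genes for each list past camera or with members past the threshold adjusted over the list alone. Unnamed probe sets and those with several genes were counted only.

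The procedure was tested on simulated data made from the measured means, spreads and array-to-array differences in noise, over 12505 genes. In the simulation of miR-376a*A against control, 53.1% of genes changed 1.5-fold, 78.0% of those changed 2-fold and 92.6% of those changed 3-fold were recovered. For miR-376a*G against control the shares were 39.7%, 75.0% and 95.6%, and for miR-376a*A against miR-376a*G they were 42.2%, 72.0% and 90.7%. False calls made up 11.9%, 16.2% and 1.46% of the simulated calls in these comparisons, in that order, so the nominal level was exceeded in both comparisons with the control group, whose arrays differed most among themselves. These shares are of 168, 167 and 137 calls, and no simulation was repeated. Such a share depends on how many genes change, so it need not hold for the measured counts. Genes sharing a simulated list shift of 0.2 on the log2 scale were recovered as a list, with 0 other lists called. Genes were drawn independently in this run. It therefore cannot show how camera behaves where the genes of a list are correlated.

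The labels give the groups the same replicate numbers. Between miR-376a*G and control the deviations of the 3 same-numbered pairs of arrays from their group means correlated with r of 0.125 to 0.187, all over the limit of 0.1 for treating the arrays as paired, while the labels name no shared culture or day. The values with the replicate number as a block are therefore given beside the results of that comparison that they change. A differently numbered pair there, miR-376a*G replicate 2 and control replicate 3, also passed the limit (r = 0.140), while the other such pairs lay below it. Between miR-376a*A replicate 3 and control replicate 1 r was 0.371. An r over the limit alone thus does not show that arrays were paired.

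Alternatives covered the normalization, the pseudocount, the filter on dim probe sets, the choice of probe set, the arrays in the fit, the variance model, array weights, the replicate number as a block, the threshold and each array left out in turn. An array left out of a fit had still taken part in the quantile normalization, the filter and the choice of probe set. A planned test of seed-match sites in 3' untranslated regions was not run, as no transcript sequences were used here. Figures were drawn with matplotlib 3.10.9.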

Results

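Gene expression was measured in SW1783 glioma cells 24 h after transfection with miR-376a*A, miR-376a*G or a control miRNA, in 3 arrays per group. The 2 forms of miR-376a* differ by a single base in the seed, the part of a miRNA that pairs with its targets: A is the unedited base, and G stands in for inosine, which A-to-I RNA editing leaves at that position. The study's stated comparison is each form against the control transfection, and the arrays also allow the 2 forms to be set against each other. Median deposited signal per array was between 18.8 and 24.0. Rank correlation over all probe sets was between 0.960 and 0.970 at its lowest and highest among 8 of the arrays. Control replicate 1 stood apart, with a highest rank correlation of 0.941 with any other array and a maximum signal of 7191, against 3601 to 4374 on the other arrays. In this array 772 genes lay at least 2-fold from the mean of control replicates 2 and 3 (556 lower and 216 higher), while 25 genes lay that far apart between replicates 2 and 3.

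The miR-376a*A transfection lowered RRAS2, a Ras-family GTPase, from a signal of 751 ± 63.0 (SD, n = 3) in control cells to 149 ± 20.7, a 4.70-fold difference. TOR1B, an ATPase of the endoplasmic reticulum, fell from 548 ± 51.9 to 123 ± 4.79 (SD, n = 3), and BZW1, a regulator of translation, fell from 1339 ± 69.3 to 398 ± 19.9. On the log2 scale the changes were -2.23 (SE 0.12), -2.04 (SE 0.11) and -1.71 (SE 0.08), with limma adjusted p = 7.45e-06 for each. In the other direction NUP37, a nuclear pore protein, rose from 196 ± 7.36 to 751 ± 27.4 and CAV2, caveolin-2, from 504 ± 32.0 to 1558 ± 106 (SD, n = 3), changes of 1.85 (SE 0.10) and 1.58 (SE 0.08), with adjusted p = 7.45e-06 for both in limma.

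The other large falls were in TVP23B (-1.74), VMA21, an assembly factor of the vacuolar proton pump (-1.71), PITRM1, a mitochondrial protease (-1.63), SEC23B, a coat protein of vesicles leaving the endoplasmic reticulum (-1.60), and RSPRY1 (-1.46). They were followed by the metal transporter SLC39A14 (-1.44), BRI3BP (-1.39), the microtubule-severing protein KATNAL1 (-1.38) and SKP2, an F-box subunit of a ubiquitin ligase (-1.37). Other probe sets of VMA21 and KATNAL1 gave 0.09 and 0.08, neither past the threshold. The largest rise was in the lipid phosphatase MTMR6 (2.24, SE 0.34). ATL3, which shapes the endoplasmic reticulum (1.84), WDFY1 (1.83), the cytokine IL11 (1.82), SEC22C (1.78), the palmitoyltransferase ZDHHC20 (1.69), the ubiquitin ligase NEURL1B (1.68), the mitochondrial ribosomal protein MRPS14 (1.68), DPY19L4 (1.61) and the DNA topoisomerase TOP2A (1.58) also rose. Another probe set of DPY19L4 gave -0.10 without passing the threshold. Adjusted p in limma was at most 0.0334 for these genes.

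Of 37 genes of the G2/M list, 7 were higher with miR-376a*A than in control over all genes tested and 10 adjusted over the list alone, with 0 lower in limma's test; CCNA2, cyclin A2, rose by 1.34, MKI67 by 0.66 and CDCA3 by 0.60. The list shifted upwards in camera (adjusted p = 6.62e-07, median 0.20, 32 of 37 genes above 0), with adjusted p = 0.0903 under an estimated correlation. Of 34 S phase genes, 2 rose over all genes tested and 4 adjusted over the list alone, with GINS2 at 0.42 and TYMS at 0.24 (camera adjusted p = 9.60e-05, median 0.14; adjusted p = 0.0903 with an estimated correlation). A second probe set of GINS2 gave -0.21, not past the threshold. The NF-kappaB list holds 23 measured genes, cytokines and others regulated by NF-kappaB such as ICAM1 and PTGS2. Of these CXCL8 rose (0.70) and 3 passed adjusted over the list alone (camera adjusted p = 0.0166, median 0.18, and adjusted p = 0.138 with an estimated correlation). The cholesterol list holds 19 measured genes, synthesis enzymes and others such as INSIG1 and LPIN1. Of these INSIG1, a sterol-sensing regulator, fell by 0.87 and 4 fell adjusted over the list alone, DHCR7 (-0.41), IDI1 (-0.38) and MVK (-0.52) among them (camera adjusted p = 0.0193, median -0.17, and adjusted p = 0.138 with an estimated correlation). Another probe set of IDI1 gave 0.17 without passing. Without control replicate 1, the same 4 lists passed, with camera adjusted p of 2.56e-06, 0.000325, 0.00241 and 0.0306 in this order (adjusted p = 0.335 to 0.403 with an estimated correlation). Over all genes tested, 15 G2/M genes were then higher and 1 lower, 10 S phase and 6 NF-kappaB list genes were higher, and 7 cholesterol genes were lower and 1 higher. The NF-kappaB list no longer passed without control replicate 3 (camera adjusted p = 0.119), nor the cholesterol list without miR-376a*A replicate 1 (0.0561) or control replicate 2 (0.0836).

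Over 12505 genes, 417 passed limma's test for miR-376a*A against control, 244 higher and 173 lower, of which 57 and 39 changed at least 2-fold. With arrays centred on their medians in place of quantile normalization, 227 were higher and 108 lower. Leaving out control replicate 1 gave 1669 genes, 866 higher and 803 lower (45 and 65 at least 2-fold), which included all 417, and leaving out miR-376a*A replicate 1, 2 or 3 gave 178, 183 or 176. Fitting only the 6 arrays compared gave 156 genes and weighting the arrays by their quality gave 2315. When the comparison was simulated 11.9% of 168 calls were false, a share that need not hold for the counts here.

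**Figure D1:**
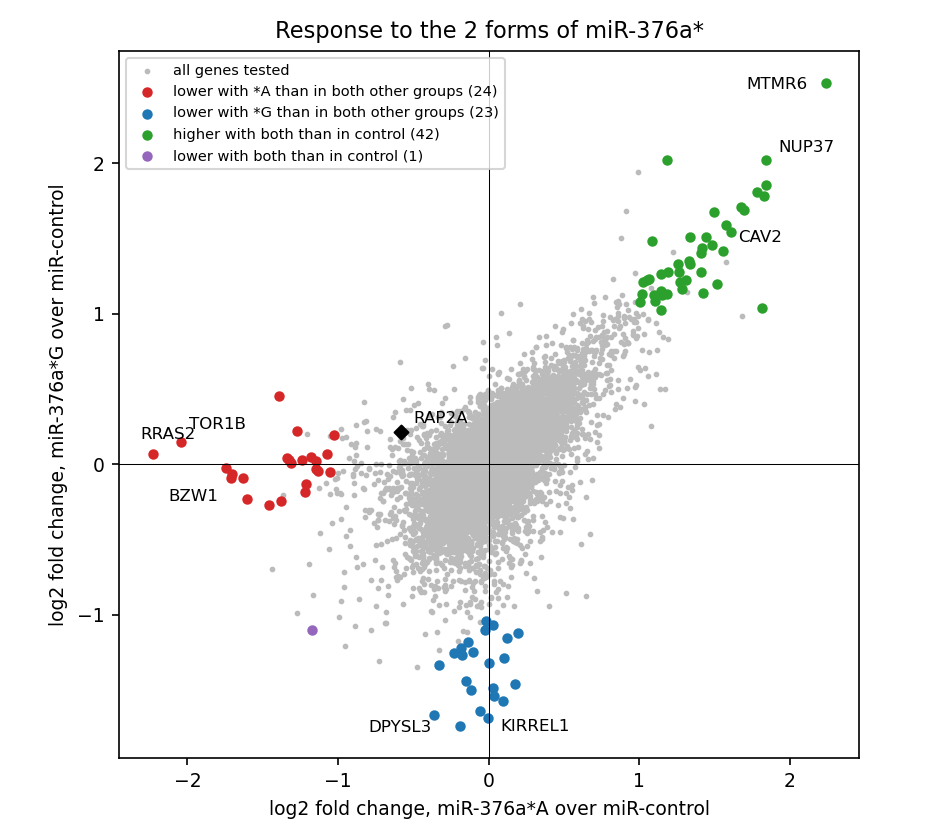
Log2 fold change of each of 12505 genes with miR-376a*A (horizontal) and miR-376a*G (vertical) over control. Coloured points are genes past the threshold and at least 2-fold changed: 24 lower with miR-376a*A than in both other groups, 23 lower with miR-376a*G than in both other groups, 42 higher with both forms than in control and 1 lower with both; the diamond marks RAP2A at -0.58 and 0.22.

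With miR-376a*G, DPYSL3, a cytoskeletal regulator of axon guidance, fell from a signal of 1488 ± 141 (SD, n = 3) in control cells to 434 ± 30.0, the adhesion protein KIRREL1 fell from 542 ± 16.7 to 162 ± 17.1, and the tyrosine kinase ABL1 fell from 793 ± 169 to 248 ± 3.81 (SD, n = 3). The log2 changes were -1.74 (SE 0.08), -1.69 (SE 0.11) and -1.64 (SE 0.15), with limma adjusted p of 6.65e-06, 7.02e-05 and 0.000320. MTMR6 rose from 99.8 ± 53.6 to 572 ± 14.8 (2.53, SE 0.34), NUP37 from 196 ± 7.36 to 845 ± 70.3 (2.02, SE 0.10) and CAV2 from 504 ± 32.0 to 1530 ± 97.5 (1.59, SE 0.08), with limma adjusted p of 0.00253, 6.65e-06 and 9.41e-06.

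LMLN fell by 1.67, CDC26, a subunit of the anaphase-promoting complex, by 1.57, PABIR2 by 1.54 and the receptor ROR1 by 1.5. The zinc transporter SLC30A6 fell by 1.49, ACVR1, a receptor for bone morphogenetic proteins, by 1.46, GPR157 by 1.44, TPRG1L by 1.35 and CCDC32 by 1.33. Other probe sets of PABIR2, ROR1 and CCDC32 gave 0.21, 0.09 and 0.18, none past the threshold. Rises were found for the lysosomal membrane protein TMEM106B (2.02), TMEM64 (1.94), ATL3 (1.86), SEC22C (1.81), WDFY1 (1.78), MRPS14 (1.71), ZDHHC20 (1.69), PLPPR4 (1.68) and LAMTOR3, a scaffold of lysosomal growth signalling (1.68). Of 5 other probe sets of SEC22C, 2 gave -0.17 and -0.15 without passing. The limma adjusted p of these genes was at most 0.0146.

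Of the 37 G2/M genes, 9 were higher with miR-376a*G than in control over all genes tested and 22 adjusted over the list alone, with CCNA2 at 1.51, MKI67 at 1.00, CDCA3 at 0.69 and CCNB2, cyclin B2, at 0.50. The list had a median of 0.34, with 36 of 37 genes above 0 (camera adjusted p = 5.91e-13; adjusted p = 0.0250 with an estimated correlation). Of 34 S phase genes, 4 rose over all genes tested and 9 adjusted over the list alone: GINS2 (0.70), ORC1 (0.62), POLE2 (0.44) and RFC4 (0.35) led, with the second probe set of GINS2 at -0.11 (camera adjusted p = 8.15e-07, median 0.23; adjusted p = 0.0369 with an estimated correlation). Of the 23 genes of the NF-kappaB list, CXCL8 (1.07), LIF (1.01) and PTGS2 (1.00) rose and CSF1 fell by 0.67. Adjusted over the list alone, 7 were higher and 2 lower (camera adjusted p = 0.0158, median 0.32, and adjusted p = 0.129 with an estimated correlation). Among 30 genes of hypoxia and glycolysis, NDRG1 (-0.64), PFKFB4 (-0.67) and the glucose transporter SLC2A1 (-0.38) fell, with 6 lower adjusted over the list alone (camera adjusted p = 0.0158, median -0.06; adjusted p = 0.129 with an estimated correlation). INSIG1 (-0.68) and LPIN1 (-0.39), neither an enzyme of cholesterol synthesis, fell among 19 genes of the cholesterol list, with 4 lower adjusted over the list alone (camera adjusted p = 0.0366, median -0.14, and adjusted p = 0.129 with an estimated correlation). Without control replicate 1 these 5 lists had camera adjusted p of 6.58e-12, 2.44e-06, 0.00414, 0.0132 and 0.0423 in the order given, and the integrin and focal adhesion list also passed (adjusted p = 0.0407, against 0.0729 with all arrays). With an estimated correlation none of these 6 lists passed without that array: the adjusted p was 0.169 for G2/M, 0.305 for S phase and 0.305 to 0.481 for the others. For the integrin list it was 0.416 with all arrays. Over all genes tested, 23 G2/M, 13 S phase and 8 NF-kappaB list genes were then higher, and 8 hypoxia, 5 cholesterol and 9 integrin genes were lower. In the other direction were 1 NF-kappaB list, 1 hypoxia, 1 cholesterol and 3 integrin genes. Without control replicate 3 the NF-kappaB, hypoxia and cholesterol lists no longer passed (camera adjusted p = 0.0732, 0.0718 and 0.0718). The same held for the NF-kappaB list without miR-376a*G replicate 3 (0.0556) and the hypoxia list without miR-376a*G replicate 1 (0.0666). It also held for the cholesterol list without miR-376a*G replicate 2 (0.0573) or 3 (0.0831), without control replicate 2 (0.112) or without normalization (0.0577). With the replicate number as a block the cholesterol list no longer passed (adjusted p = 0.0570). The block also ended the calls of ORC1, POLE2, PTGS2, NDRG1, PFKFB4, SLC2A1 and LPIN1. Their limma adjusted p were then 0.0553, 0.0807, 0.0531, 0.0604, 0.0639, 0.0818 and 0.113 in this order.

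For miR-376a*G against control 578 genes passed limma's test, 313 higher and 265 lower, of which 63 and 40 changed at least 2-fold. With the replicate number as a block 360 genes passed. With arrays centred on their medians 288 were higher and 162 lower. Leaving out control replicate 1 gave 2124 genes, 1065 higher and 1059 lower (50 and 61 at least 2-fold), all 578 among them. Leaving out miR-376a*G replicate 1, 2 or 3 gave 240, 235 or 259, and leaving out miR-376a*A replicate 1 or 2 gave 385 or 351. The 6 arrays compared gave 204 genes when fitted without the other miRNA group and 167 with the block as well. Array weights gave 2427, and a minimum change of 1.5-fold left 373. In the simulation 16.2% of 167 calls were false, a share that need not hold for the counts here.

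**Figure D2:**
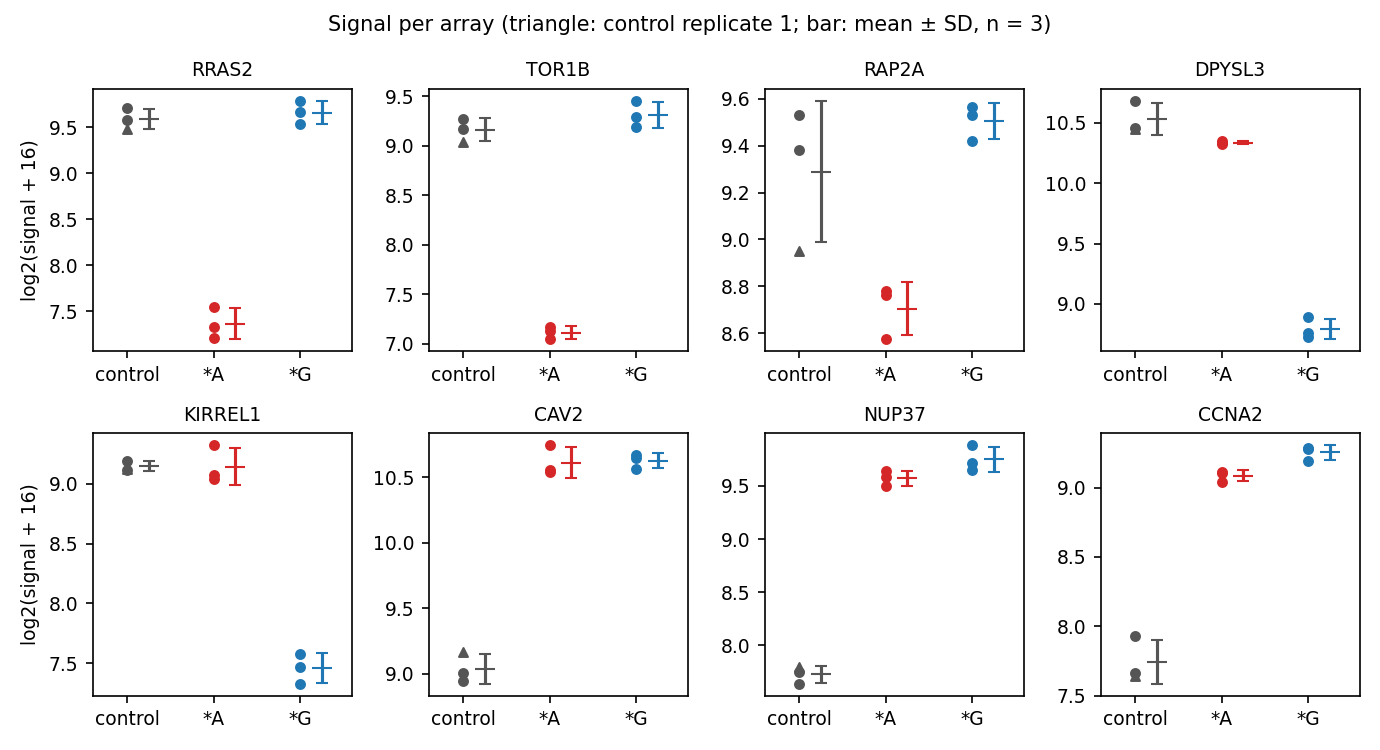
Quantile-normalized log2(signal + 16) of 8 genes on each of 9 arrays, with the mean and SD (n = 3) of each group; triangles mark control replicate 1. RRAS2 and TOR1B were lower in the 3 miR-376a*A arrays than in all others, DPYSL3 and KIRREL1 in the 3 miR-376a*G arrays, and CAV2, NUP37 and CCNA2 were higher in all 6 treated arrays than in the 3 controls.

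Of the 155 genes lower with miR-376a*A than with miR-376a*G, 108 were also lower than in control, and of the 174 higher ones, 119 had been lowered against control by miR-376a*G. RRAS2 was 4.93-fold lower with miR-376a*A than with miR-376a*G (149 ± 20.7 against 792 ± 69.8, SD, n = 3; log2 -2.30, SE 0.12) and TOR1B 4.58-fold lower (123 ± 4.79 against 623 ± 57.9; log2 -2.20, SE 0.11). KIRREL1 was 3.22-fold higher with miR-376a*A (554 ± 56.9 against 162 ± 17.1, SD, n = 3; log2 1.69, SE 0.11) and ABL1 3.00-fold higher (775 ± 29.7 against 248 ± 3.81; log2 1.58, SE 0.15). The limma adjusted p of these 4 genes were 8.61e-06, 8.05e-06, 4.75e-05 and 0.000379.

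BRI3BP (-1.84), TVP23B (-1.72), VMA21 (-1.65), BZW1 (-1.62), PITRM1 (-1.54), the zinc transporter SLC39A10 (-1.5), the growth factor FGF2 (-1.41), the tRNA-modifying enzyme YRDC (-1.38), SEC23B (-1.37) and COMMD2 (-1.36) were also lower with miR-376a*A. CDC26 (1.67), ACVR1 (1.63), PABIR2 (1.57), DPYSL3 (1.54), EMP2 (1.52), SLC30A6 (1.51), RIDA (1.39), ROR1 (1.38), the transcription factor UBP1 (1.37) and SFXN1, a mitochondrial serine transporter (1.34), were higher. Other probe sets of VMA21 (0.13), SLC30A6 (-0.16) and ROR1 (-0.07) pointed the other way without passing the threshold.

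Of 28 integrin and focal adhesion genes, 3 were higher with miR-376a*A than with miR-376a*G over all genes tested, the caveolin CAV1 (0.35), the integrin subunit ITGB3 (0.51) and LPP (0.55), and 5 adjusted over the list alone, with VCL, vinculin, at 0.37 (camera adjusted p = 0.00169, median 0.15; adjusted p = 0.307 with an estimated correlation). Another probe set of LPP gave -0.15, not past the threshold. Against control, VCL fell with both forms (-0.68 with miR-376a*A and -1.06 with miR-376a*G). The G2/M list had a median of -0.15 between the 2 forms (camera adjusted p = 0.00169; adjusted p = 0.307 with an estimated correlation), and 0 of its 37 genes passed limma's test on their own, over all genes or adjusted over the list alone, and 5 had an unadjusted p under 0.05. Over all genes tested, 4 G2/M genes were lower and 6 integrin genes higher without control replicate 1 (adjusted p = 0.631 for both lists with an estimated correlation). With all arrays CCNB2 was at -0.23, BIRC5 at -0.20, CDCA8 at -0.21 and MKI67 at -0.34, the latter with another probe set at 0.00.

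In the direct comparison 329 genes passed limma's test, 174 higher and 155 lower with miR-376a*A, of which 34 and 39 differed at least 2-fold. Leaving out miR-376a*A replicate 1, 2 or 3 gave 156, 146 or 143 genes and miR-376a*G replicate 1, 2 or 3 gave 157, 154 or 180. Control replicate 1 entered this comparison through the shared estimate of the spread: 1210 genes passed without that array, all 329 among them, 1292 when only the 6 arrays compared were fitted and 1656 with array weights.

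RAP2A, a Ras-related GTPase, is a target of miR-376a*A chosen by the study, so its change is not independent evidence of direction. Its signal was 402 ± 31.0 with miR-376a*A, 712 ± 28.5 with miR-376a*G and 609 ± 132 in control cells (SD, n = 3). RAP2A was lower with miR-376a*A than with miR-376a*G by 1.74-fold (log2 -0.80, SE 0.14, limma adjusted p = 0.0149). Leaving out any of the 6 treated arrays ended this call, with adjusted p of 0.0548 to 0.0922, as did averaging the probe sets of the gene (0.144); over 20 alternatives, 8 of them chosen for single genes after the data were seen, the adjusted p ran from 6.55e-06 to 0.144. Against control the change was -0.58 with miR-376a*A (SE 0.14, adjusted p = 0.0572 in limma) and 0.22 with miR-376a*G (SE 0.14, adjusted p = 0.480), neither past the threshold over all genes. Control replicate 1 had a RAP2A signal of 461, against 652 and 715 in the other controls, and without it the changes were -0.75 (adjusted p = 0.000274) and 0.05 (adjusted p = 0.764). The difference between the 2 forms, which this array enters in the fit through the shared estimate of the spread, then had limma adjusted p = 7.65e-05. Over 20 alternatives that kept this gene's test, the adjusted p against control ran from 5.75e-05 to 0.262 with miR-376a*A, 3 of them past the threshold, and from 0.209 to 0.764 with miR-376a*G. A second probe set of RAP2A gave -0.39, 0.32 and -0.71 for miR-376a*A, miR-376a*G and their difference (limma adjusted p = 0.405, 0.451 and 0.131), and a dimmer probe set gave -0.02, -0.13 and 0.11, none past the threshold.

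Genes lowered by each form and genes raised by both were counted from the tests themselves. With miR-376a*A, 108 genes were lower than in control and lower than with miR-376a*G, and 7 were higher than in both; with miR-376a*G these counts were 119 and 11. Without control replicate 1 the counts were 310 and 106 with miR-376a*A and 417 and 115 with miR-376a*G. Leaving out any 1 of the 6 treated arrays gave 49 to 71 falls and 1 to 4 rises with miR-376a*A, and 58 to 65 falls and 3 to 4 rises with miR-376a*G. The replicate block gave 5 rises with each form, and median centring 68 falls with miR-376a*A. Rises with miR-376a*A and miR-376a*G numbered 14 and 16 with the mean of a gene's probe sets, and 11 and 15 with eBayes without an intensity trend. Array weights gave 396 falls and 182 rises with miR-376a*A and 515 and 187 with miR-376a*G. At 2-fold or more in both tests the falls numbered 24 and 23 and the rises 0 and 0. Against control, 184 genes rose with both forms and 26 fell with both, while 0 moved in opposite directions; lists drawn independently would share 6.11 and 3.67. Without control replicate 1 there were 554 shared rises, 339 shared falls and 22 genes that moved in opposite directions. Leaving out any 1 of the treated arrays gave 80 to 106 shared rises and 11 to 14 shared falls. The replicate block gave 116 and 17, median centring 168 and 12, and 15 shared falls were left without control replicate 3. Array weights gave 762 shared rises, 408 shared falls and 41 genes in opposite directions. At least 2-fold changes shared by both forms were 42 rises, CAV2, NUP37, MTMR6, ATL3 and CCNA2 among them, and 1 fall, in UGDH, an enzyme of sugar-nucleotide synthesis singled out after its value was seen.

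Across genes, the fold changes of the 2 forms against control correlated with r = 0.659. Simulated groups without any effect, set against a shared simulated control group, gave a mean r of 0.850. Each gene was drawn independently with its own spread in each group, whereas measured genes are not independent replicates. The covariance was 0.0519, against 0.0366 in the simulation, a difference of 0.0153. Without control replicate 1 the correlation was 0.656, against a simulated mean of 0.660, and the covariance was 0.0513 against 0.0125, a difference of 0.0388. With 3 controls no split leaves a pair of arrays on each side, so part of the overlap of 184 and 26 genes may come from the shared controls.

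**Figure D3:**
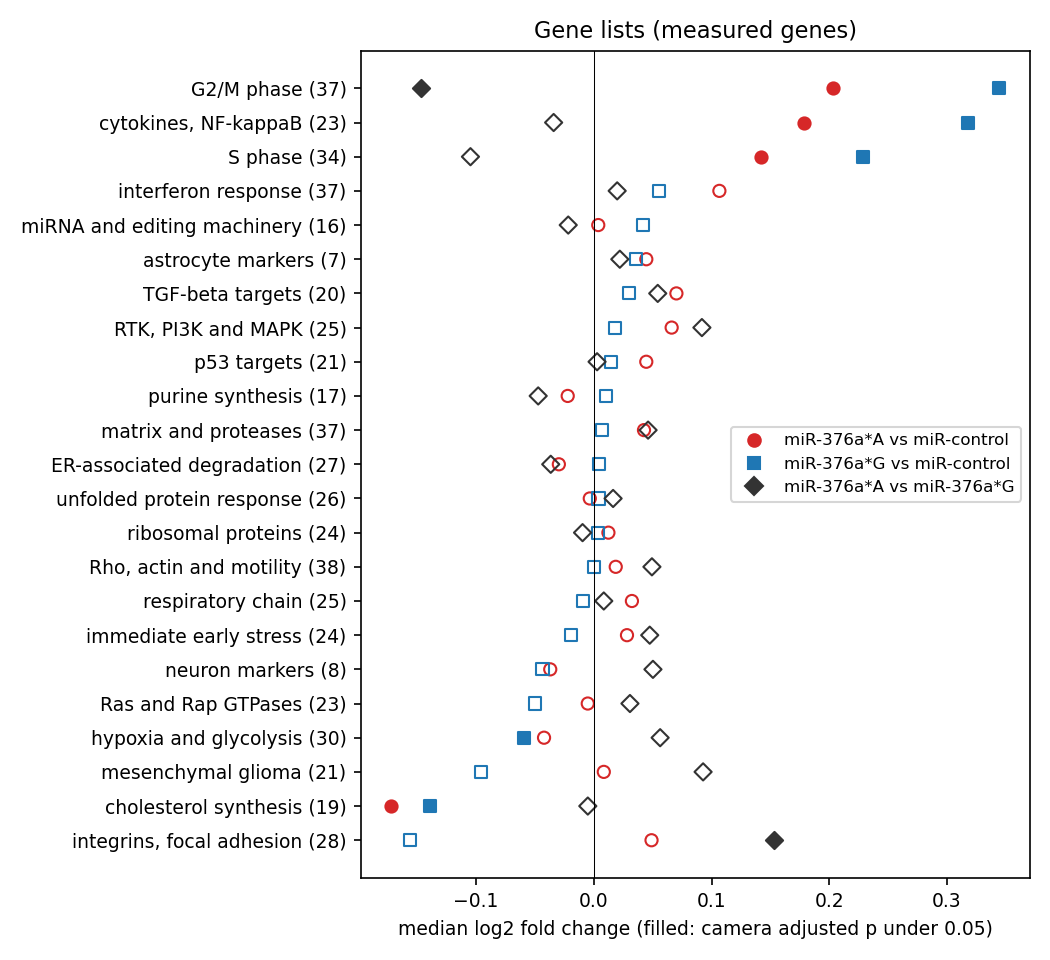
Median log2 fold change of the measured genes of 23 gene lists in 3 comparisons, with the number of measured genes in brackets; filled symbols have a camera adjusted p under 0.05 with the preset correlation, while 0, 2 and 0 lists pass with an estimated correlation, the 2 being G2/M and S phase with miR-376a*G. G2/M genes lay at 0.20 with miR-376a*A and 0.34 with miR-376a*G over control, and integrin and focal adhesion genes at 0.15 with miR-376a*A over miR-376a*G.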

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

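Probe sets without a single gene symbol stayed outside the comparisons by gene and were tested on their own with limma. Of 4389 such probe sets past the brightness filter, 36 differed between miR-376a*A and control (22 higher and 14 lower), 94 between miR-376a*G and control (47 higher and 47 lower) and 48 between the 2 forms (32 higher and 16 lower with miR-376a*A). They came to attention because they hold a signal in data that the gene comparisons do not use. The transcripts were not identified here.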

How the results depend on the processing

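Normalization, pseudocount, dim-probe filter, probe-set summary and variance model kept each total of changed genes within 1.5 times its value, although centring arrays on their medians lowered the falls against control from 173 to 108 and from 265 to 162; medians of signal were low, and the number of arrays limits precision. Chosen after the data were seen were, for lists and the shared response, no normalization; for single genes, no normalization, median centring, both other filters, the mean of probe sets, both other variance models and array weights; and the block on 6 arrays and the estimated correlation without single arrays; the seed-site test and its alternatives were not run. For miR-376a*A against control, miR-376a*G against control and the 2 forms against each other, array weights gave 2315, 2427 and 1656 genes; fitting only the 6 arrays compared gave 156, 204 and 1292; an unadjusted p under 0.01 gave 867, 1073 and 666. An adjusted p under 0.1 gave 643 and 948 genes against control and a minimum of 1.5-fold left 373 with miR-376a*G, since the threshold itself moved. Leaving out each array in turn gave 176 to 1669, 235 to 2124 and 143 to 1210 genes, the highest each time without control replicate 1 and the lowest without miR-376a*A replicate 3, miR-376a*G replicate 2 and miR-376a*A replicate 3. Gene lists past the threshold numbered 4, 5 and 2, with 3 to 4, 2 to 6 and 2 to 3 when single arrays were left out (2 and 3 for miR-376a*G without control replicate 3 and without miR-376a*G replicate 3), and 0, 2 and 0 with an estimated correlation. The correlation of the 2 responses ranged from 0.634 to 0.754. Except where the construction shows it (fewer arrays, another threshold), the cause was not tested.

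The replicate number as a block gave 292, 360 and 223 genes in these comparisons, and 167 for miR-376a*G against control on its 6 arrays. In that comparison 5 of 6 arrays correlated best with their own number, and of its calls for lists and genes under the naming rule the block ended those of the cholesterol list and 13 genes and changed no other. The numbers did not pair the arrays of miR-376a*A with control (r -0.36 to 0.03) or with miR-376a*G (-0.10 to -0.03).

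Among 210 pairs of a named gene and a comparison, 0 changed direction under any setting other than another probe set. Much of this was fixed in advance. The block, the variance models and the filters on dim probe sets leave a fold change as it is. Genes whose arrays do not overlap between the groups cannot reverse when a single array is left out. With probe sets under the 75th percentile left out, only 195 of the pairs had a value. Leaving out a single treated array ended 42 to 52 of their calls, while leaving out control replicate 1 ended 0 and added 44. Of 247 other probe sets of these genes, 107 kept direction and side of the threshold, 99 kept direction without passing where the gene had passed, 8 passed where it had not, and 33 pointed the other way, none past the threshold; the cause was not tested. For miR-376a*A against control these were AXL 0.10, CTTN 0.30, 0.013 and 0.018, DPY19L4 -0.10, FAS -0.011, FBXW7 0.062, GINS2 -0.21, IDI1 0.17, KATNAL1 0.079, PARVA -0.26 and -0.42, and VMA21 0.095. For miR-376a*G against control they were AXL 0.20, CCDC32 0.18, FAS -0.17, FOSL2 0.044, GINS2 -0.11, IDI1 0.19, PABIR2 0.21, PARVA -0.13 and -0.30, RAP2A -0.13, ROR1 0.092, SEC22C -0.17 and -0.15, and TNFRSF10B 0.16. For miR-376a*A against miR-376a*G they were LPP -0.15, MKI67 0.0027, RAP2A 0.11, ROR1 -0.068, SLC30A6 -0.16 and VMA21 0.13.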

Other observations

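Other gene lists did not pass camera, yet held single genes that changed. Both forms raised the cadherin CDH2 (1.34 with miR-376a*A and 1.33 with miR-376a*G), the Ras-related GTPase RAP2B (0.69 and 0.82), the receptor TGFBR2 (0.69 and 0.53) and XBP1, a transcription factor of the unfolded protein response (0.61 and 0.60). Both lowered the receptor kinase AXL (-0.38 and -0.43), haem oxygenase HMOX1 (-0.55 and -0.69) and the phosphatase DUSP5 (-0.49 and -0.50). With miR-376a*A, non-muscle myosin MYH9 fell by 0.85, ERLIN2, a protein of endoplasmic reticulum degradation, by 0.90 and CCN1 by 0.41, while CDKN1A (0.53) and FAS (0.56) rose; 2 of 21 p53 target genes passed. With miR-376a*G, the death receptor TNFRSF10B fell by 1.12, succinate dehydrogenase subunit SDHD by 0.98, the collagen COL4A1 by 0.92 and the kinase PIK3CB by 0.65, while EGR1 (1.5), CCN2 (0.85) and the protease PLAU (0.48) rose. Directly between the forms, MYH9 (-0.79), ERLIN2 (-0.92), CCN1 (-0.42), TNFRSF10B (1.31), SDHD (1.04), COL4A1 (0.80) and CCN2 (-0.80) also passed limma's test. Other probe sets of AXL, FAS and TNFRSF10B pointed the other way without passing. With the replicate number as a block, DUSP5 and TGFBR2 no longer passed for miR-376a*G against control (limma adjusted p = 0.0620 and 0.0515).

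Among 37 interferon response genes 0 passed limma's test in any of the 3 comparisons, over all genes or adjusted over the list alone, with list medians of 0.11, 0.06 and 0.02; 4, 2 and 1 had an unadjusted p under 0.05. The arrays with miR-376a*A differed on this list: its mean over control was 0.38 in replicate 3, against -0.05 and -0.15 in replicates 1 and 2. Without replicate 3 the list's median was -0.18 with miR-376a*A over miR-376a*G (camera adjusted p = 0.00253 with the preset correlation, against 0.853 with all arrays; adjusted p = 0.397 with an estimated correlation), with 0 genes past limma's test and 4 at an unadjusted p under 0.05. Leaving out control replicate 3 let 1 gene pass between miR-376a*A and control. The estimated correlation between genes of the list was 0.350. Of 8 measured neuron markers, SNAP25 (1.12 and 0.94) and STMN2 (0.62 and 0.62) rose with both forms and SYT1 fell by 1.10 with miR-376a*G; with the replicate block STMN2 had an adjusted p of 0.0773 in limma for miR-376a*G. Of 7 astrocyte markers 0 passed over all genes in limma, with 1, 1 and 0 at an unadjusted p under 0.05 and the same numbers adjusted over the list alone; without control replicate 1, 2, 2 and 0 passed over all genes, all higher. Fewer than 5 genes were measured for endothelial, epithelial, immune and oligodendrocyte markers, and 0 of them passed limma's test over all genes, with at most 1 per list and comparison at an unadjusted p under 0.05. Adjusted over the list alone, 1 epithelial gene was higher with miR-376a*A than with miR-376a*G. Without control replicate 1 it was 1 over all genes there, and against control with miR-376a*A 1 epithelial gene was higher and 1 endothelial gene lower.

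The interferon list without single arrays and the tests below on scaling of the outlying control array, on shared rises and on falls, and the counts over 21 settings and at any size were chosen after the results were seen; the others were written down before theirs. Each comparison of 3 with 3 arrays has 10 splits, too few for a share under 0.05. With miR-376a*A and control, 1 of the 10 splits, the real one, gave as many as 417 genes, and the highest of the others gave 0. For miR-376a*G and control it was 1 of 10, with 578 genes against 0, also in the 3 other splits that part each same-numbered pair, and for the 2 forms 1 of 10, with 329 against 0.

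Control replicate 1 stood apart from the other 8 arrays. A change of scale that keeps the order of probe sets was argued against by its rank correlations, at most 0.941 where the other 8 arrays had at least 0.960. Independent noise of single probe sets as the only source was argued against by its deviations from the other controls. These correlated between 2 probe sets of a gene with r = 0.259 across 5993 genes (95% limits 0.235 and 0.282), against 0.114 for control replicate 2 minus 3. An r of this size leaves room for such noise as a large part of the deviation. A mislabelled treated sample was argued against too: over 35 genes lowered by miR-376a*A the array showed a median of 0.243 of the fall (95% limits 0.110 and 0.435), and over 26 genes lowered by miR-376a*G 0.152 (limits -0.00 and 0.266). These limits come from resampling the genes of a single array, so they do not measure the spread between arrays. The deviation and the fall were both taken against control replicates 2 and 3. Partial mixing of samples was not tested. The 3' to 5' signal ratios of GAPDH and ACTB were 0.910 and 0.912 on this array. On the other arrays they ran from 0.867 to 0.934 and from 0.861 to 0.910, so these genes showed no sign of RNA degradation particular to it. A difference in the culture, the RNA or the labelling was otherwise not tested and stays open.

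Changes of at least 2-fold shared by both forms were mostly rises. The outlying control array alone does not account for this, since 31 rises and 5 falls were left with it out of the fit. Nor does quantile normalization alone, with 43 rises and 2 falls without it. The array and the normalization were not left out together. With all arrays there were 42 rises and 1 fall, and over 21 settings 23 to 58 rises and 0 to 5 falls; among changes of any size the outlying array weighs more, with 184 and 26 with it and 554 and 339 without it. Transcripts lowered by the control duplex may look like rises in both other groups, and this cannot be told apart from a rise caused by both forms, because every control array carries that duplex and no untransfected cells were analysed here.

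Changes of at least 2-fold that set 1 form apart from both other groups were mostly falls, 24 with miR-376a*A and 23 with miR-376a*G, against 0 rises with either. Without control replicate 1 there were 61 falls and 1 rise, and without normalization between arrays 48 falls and 0 rises. This argues against either alone as the cause at this size. At any size, rises numbered 106 and 115 without that array, against 310 and 417 falls. Over 21 settings the falls ranged from 11 to 35 and from 10 to 30, and the rises from 0 to 0 and from 0 to 2. A hypothesis for these genes, RRAS2, TOR1B, DPYSL3 and KIRREL1 among them, is that each form may repress its own transcripts through its seed; it was found on these data and not tested, since sites for the 2 seeds were not searched here.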
